A study of Canis lupus familiaris with 8 samples.

How the data were processed

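The series holds 8 arrays of a canine 1-colour Agilent design, 2 for each of 4 groups. The arrays were scanned and quantified with Agilent Feature Extraction 11.5.1.1, per the file headers. The authors' scanner files give a processed signal for each spot as an intensity, with the median signal, the background median and flags, per the file headers. The deposited series matrix gives log2 values. Set against the scanner files, these closely match the log2 processed signal less each array's 75th percentile, then centred on each probe's median over the 8 arrays. Taken relative to Stylo CSC replicate 1, the difference had an SD of at most 0.011 over 10563 probes. The column medians of the matrix ran from -0.27 to 1.01. RNA was extracted with a column kit and DNase treatment, per the labels' protocols.

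Groups and replicate numbers were taken from the sample titles. Control spots and spots marked as outliers (non-uniform or population) were left out, log2 of the processed signal was averaged over the spots of a probe, and each array's 75th percentile was subtracted. No spot was saturated on any array. A probe was tested if it was well above background on both arrays of at least 1 group. Signal over background limits each value: a probe not well above background on either array of a group has only a bound there, computed from the bright group's mean and, for the dim group, the higher of the lowest well-above-background signal and the probe's own signal on each array. No fold is given where both groups were below background.

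Gene symbols came from a RefSeq gene table (assembly UU_Cfam_GSD_1.0, used for names only) matched on accession without version. It named 2353 of 43603 probes (5.40%), for 1458 symbols. Another 19070 probes carry Ensembl accessions and 3806 model RefSeq accessions, which were not named here. No coordinates are given.

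limma 3.58.1 in R 4.3.3 was used to fit the 4 group means on all 8 arrays with 1 shared spread per probe (lmFit and eBayes), and 5 contrasts were drawn. A call needed a Benjamini-Hochberg adjusted p under 0.05 over the tested probes and a change of at least 2-fold. All p-values are two-sided. These tests, the groups, the gene lists, the named-gene rule and the alternative settings, except those named in the closing part as chosen later, were fixed before the data were examined. The named genes were, for the first 3 comparisons, the 5 largest rises and falls with a symbol among calls well above background on all 4 arrays, the called member of each list with the largest change, a fixed set of 12 genes, and the 3 largest bounds in each direction. For the other contrasts only the largest rises and falls and the fixed set were used. Some genes picked by this rule and 1 gene list of the figure are not reported here, and none was put in their place. A gene is represented by its tested probe with the highest mean level. Of 31 gene lists, 25 had at least 3 tested genes. They were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. Among lists called by camera, the estimate was 0.210 for ribosomal proteins and 0.077 for inflammatory cytokines. It lay below 0.01 for interferon response (-0.057), collagens (-0.144), glycolysis (-0.027), lysosome (-0.084), heat shock (-0.047) and drug transporters (-0.127). A higher correlation therefore cannot be why these lost their calls. With an estimated correlation, camera refers its statistic to the residual degrees of freedom of 8 arrays in 4 groups. With a preset one it refers it to the number of genes. Hardly any list could pass the estimated version here, so a call lost with it does not by itself show correlated genes. Counts of members called over all tested probes equalled those adjusted over the list alone in every list of the first 2 comparisons and differed in 1 list of each of the other 3 contrasts. Median changes named for lists were checked under each scaling.

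The replicate numbers pair the groups by label only: same-numbered arrays had correlated deviations of -0.07 to 0.07, so no block entered the fit. Slide was tested as a block where a slide held both groups. Alternatives covered quantile, median, cyclic loess, detected-probe and spike-in scaling, normexp background correction with an offset of 50 (close to the 75th-percentile signal of the Stylo parent arrays), filters on dim probes, thresholds, variance models, the deposited matrix and leaving out each array. The files hold no mean signal column, so normexp was run on the median signal.

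The fit was tested on simulated arrays of 26737 probes, of which 67, 67 and 66 were changed by 1, 2 and 3 on the log2 scale. Noise was normal and independent, with no array effects. The real comparisons called far larger shares of probes, so the shares and false calls below do not carry over to them. A first pass mark for recovery of the larger changes was not reached and was replaced by other checks. For Star CSC against Star parent, 25.4%, 80.6% and 93.9% of probes changed by 1, 2 and 3 on the log2 scale were called, with 5 false calls. For Stylo CSC against Stylo parent the shares were 19.4%, 79.1% and 87.9%, with 4 false calls.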

Results

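Total RNA from a canine mammary carcinoma cell line, CMT-Stylo, and from its doxorubicin-resistant subline, CMT-Star, was profiled on 8 Cy3-labelled arrays carrying 43603 gene probes. CMT-Star was derived from CMT-Stylo by exposure to rising doxorubicin until it grew at 100 nM. From each line, cells positive for CD44 and aldehyde dehydrogenase activity with low or no CD24 had been sorted as cancer stem cells (CSC). The arrays fell into 4 groups of 2, called Stylo parent, Stylo CSC, Star parent and Star CSC, and n = 2 arrays per group holds throughout. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

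The Stylo parent arrays were dimmer than the other 6. Their 75th percentile of processed signal was 88.8 and 69.5, against 297 to 540 on the others, and 47.4% and 46.7% of their spots were well above background, against 55.5% to 60.7%. The shape of their signal differed too: the brightest 100 spots held 32.4% and 33.7% of the signal, against 12.7% to 22.7% on the others. Subtracting a constant per array does not remove a difference in shape. Replicate arrays correlated at 0.981 or more across tested probes, while Stylo parent arrays correlated with arrays of other groups at 0.807 to 0.889. All Stylo arrays lay on slide 1 and all Star arrays on slide 2, scanned separately. Only 2353 probes could be given a gene symbol here, and 978 named genes were tested, so most measured probes carry no name below.

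**Figure D1:**
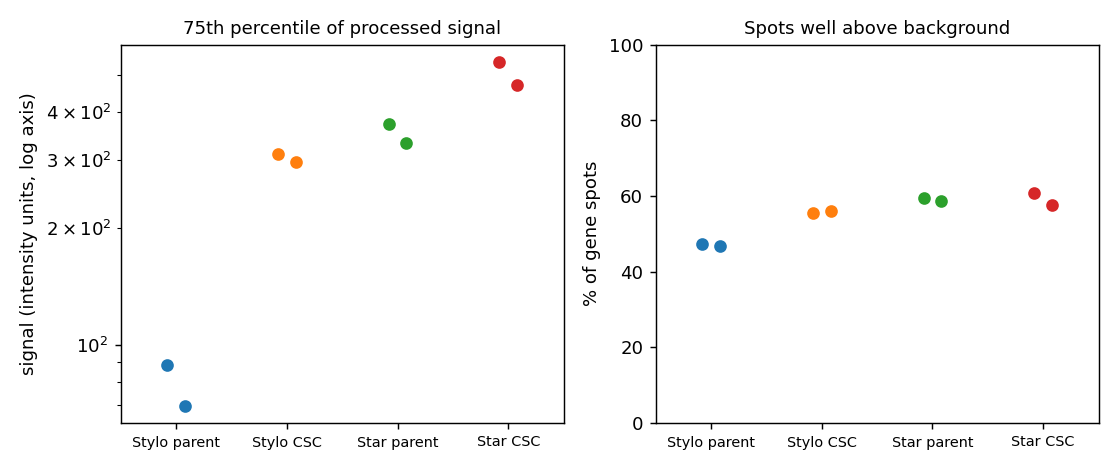
Left, 75th percentile of the processed signal of each array on a log axis in intensity units; right, percent of gene spots well above background. Each point is 1 of the 8 arrays, grouped by cell line and sort. The Stylo parent arrays, at 88.8 and 69.5, lie below the other 6.

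The first comparison asked which genes differ between the resistant subline and its parent line. Ribosomal protein genes were lower on the Star parent arrays at this scaling: all 22 tested members fell, with a median log2 fold change of -3.04 (-0.55 with quantile normalization). RPS10 fell furthest (-4.05 ± 0.11 SE). The list call was lost with quantile normalization, which equalises the shape of the signal, so the difference in shape between the arrays cannot be excluded. Lysosome and autophagy genes went the other way, with 6 of 8 higher, among them NPC1, a cholesterol exporter of lysosomes (2.93 ± 0.27). All 4 heat shock genes were higher (HSPB1, 1.99 ± 0.23), as were 4 of 8 glycolysis and hypoxia genes, such as ADM (1.84 ± 0.09). ABCB1, the drug efflux pump P-glycoprotein, was 5.74-fold higher in Star parent (log2 2.52 ± 0.11). The matrix proteoglycan DCN was 44.3-fold lower (-5.47 ± 0.10).

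Among genes well above background on all 4 arrays, large rises were in LGALS9, a galectin (6.15 ± 0.55), GCG (4.94 ± 0.22), the membrane protein STOM (4.28 ± 0.10) and IGF2R (3.98 ± 0.10). The largest falls were in MAL (-5.78 ± 0.10), SHOX (-5.76 ± 1.62), carbonic anhydrase CA2 (-5.54 ± 0.59), DCN and KLK1 (-5.17 ± 0.27). SMOC2, MX1 and DAG1 were not well above background in Stylo parent and were at least 73.0-fold, 58.5-fold and 14.6-fold higher in Star parent. HAMP, PLG and CA3 were not well above background in Star parent and were at least 72.9-fold, 34.2-fold and 19.2-fold lower there.

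Drug transporters had 3 of 5 members higher and none lower (ABCB1, MVP and ABCC5), and interferon response genes had 3 of 5 measured members higher. Neither list passed its test (adjusted p = 0.108 for each), and the interferon median turned negative with normexp (-0.06). Oxidative phosphorylation genes were lower in 4 of 4 (NDUFS8, -1.79 ± 0.15; list adjusted p = 0.221), a median that turned positive with quantile normalization (0.17) and normexp (0.27). NRF2 and glutathione genes were split, with 2 of 11 higher and 4 lower, led by the ferritin light chain FTL (-3.82 ± 0.11). Apoptosis regulators were also split, with 2 of 13 higher and 5 lower (CYCS, -2.26 ± 0.09). Of all 978 named genes tested, 201 were higher and 383 lower, so both of these splits lay near the share over all named genes. Collagens and matrix genes had 3 of 5 higher and 2 lower, and fibroblast markers, a list that shares COL1A1, COL1A2 and DCN with it, had 1 of 6 higher and 4 lower. Inflammatory cytokines and NF-kB targets had 4 of 14 higher and 4 lower, with a median that changed sign between scalings, and PTGS2 at -5.52 ± 1.58, well above background on 1 of 2 Star parent arrays.

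Further falls were measured in BIRC5, an inhibitor of apoptosis of dividing cells (-4.51 ± 0.44), the Wnt ligand WNT5A (-4.42 ± 0.38), the tight junction gene CLDN3 (-4.27 ± 0.21, well above background on 1 of 2 Star parent arrays), S100A4 (-3.12 ± 0.11), SOCS3 (-2.95 ± 0.26), PMAIP1 (-2.84 ± 0.15), NOS3 (-2.68 ± 0.10), the basal keratin KRT14 (-2.00 ± 0.18), ADIPOQ (-1.94 ± 0.23, well above background on 1 of 2 Star parent arrays) and the sterol enzyme MSMO1 (-1.38 ± 0.22). The stem cell marker PROM1 was at least 12.7-fold higher and the aldehyde dehydrogenase ALDH3A1 was 4.05-fold higher (2.02 ± 0.19). The sort marker CD44 rose by 1.08 ± 0.14, and ABCC1 stood at 0.99 ± 0.14, just under the fold limit. ABCC1 was called with median scaling (1.39), with the 75th percentile of probes detected on all arrays, here the detected-probe percentile (1.31), without Star parent replicate 1 (1.03) and without Stylo parent replicate 2 (1.06). VIM, a mesenchymal intermediate filament, was lower (-1.33 ± 0.11), but higher with quantile normalization (0.98), cyclic loess (0.62) and normexp (0.10), and not called with median scaling (-0.93). CDH1, the epithelial cadherin, and KDR were not well above background in Stylo parent and too close to it in Star parent for a bound, so no fold is given. Quantile normalization ended the calls of S100A4 (-0.39), CYCS (-0.70), NDUFS8 (-0.55) and MSMO1 (-0.42), cyclic loess those of NDUFS8 (-0.74) and MSMO1 (-0.71), and median scaling that of MSMO1 (-0.98). Normexp ended those of KRT14 (-0.86), CYCS (-0.64), NDUFS8 (-0.16) and DAG1 (0.39) and turned MSMO1 (0.18). Spike-in scaling ended the calls of KRT14 (-0.95), ADIPOQ (-0.89), NDUFS8 (-0.74), MSMO1 (-0.33) and VIM (-0.28). ALDH1A1, TYROBP and CA1 were not well above background on any array of these groups, and no fold is given.

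Of 26825 probes tested, 15168 were called, 6600 higher and 8568 lower in Star parent. The series text states 26652 entities, at a 2-fold change and p under 0.05 with no test or correction named. With no filter on dim probes the count was 26734. Lists called by camera were ribosomal proteins (adjusted p = 2.9e-05), lysosome and autophagy (0.00898), heat shock (0.0366), and glycolysis and hypoxia (0.0424). With an estimated correlation each had adjusted p = 0.351. The ribosomal call was lost with quantile normalization (0.0552) and normexp (0.106; median -1.48), and the median was -1.24 with cyclic loess. The heat shock call was lost with median scaling (0.0704), the detected-probe percentile (0.0571) and quantile normalization (0.0573). The glycolysis call was lost with median scaling (0.0574), quantile normalization (0.0552), only the arrays compared (0.0533) and without Star parent replicate 2 (0.0768). Both were lost with spike-in scaling (0.112 for heat shock and 0.204 for glycolysis). Line and slide cannot be told apart in this comparison, since each slide held a single line. Calls ended without Stylo parent replicate 1 for SHOX (adjusted p = 0.0792), PTGS2 (0.0760) and CD44 (log2 0.90), and without Stylo parent replicate 2 for SHOX (0.0537) and PTGS2 (0.0644).

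The second comparison asked what separates the sorted cells from the unsorted CMT-Stylo line. In Stylo CSC, all 5 tested collagens and matrix genes rose, with COL1A2 at 3.03 ± 0.23, the proteoglycan BGN at 3.06 ± 0.15 and DCN at 1.64 ± 0.10. Glycolysis and hypoxia genes rose in 6 of 8, led by the hypoxia-induced carbonic anhydrase CA9 (2.45 ± 0.15). Inflammatory cytokines and NF-kB targets rose in 8 of 14, among them CCL2 (2.96 ± 0.11) and CCL5 (at least 9.55-fold), and 1 fell. Ribosomal proteins fell in 21 of 22 (RPL19, -2.37 ± 0.15), and RPL4 did not pass. The inflammatory median turned to -0.03 with normexp, and the ribosomal median to 0.28 with spike-in scaling. The orphan receptor NR4A1, an immediate early gene, was at least 26.5-fold higher, and the interferon-induced MX1 at least 33.2-fold higher.

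Among genes well above background on all 4 arrays, LGALS9 (4.99 ± 0.55), the prostaglandin E synthase PTGES (4.45 ± 0.40), alkaline phosphatase ALPL (4.23 ± 0.16) and the calcium pump ATP2A2 (3.28 ± 0.18) were among the largest rises. The decoy interleukin-13 receptor IL13RA2 fell 214-fold (-7.74 ± 0.13), followed by the urokinase gene PLAU (-5.68 ± 0.21), TIMM8A (-3.74 ± 0.11), IL5 (-3.30 ± 0.12) and SELENOT (-3.12 ± 0.19). ADGRL2 was at least 70.7-fold higher than in Stylo parent, where it was not well above background. PLG, ODAM and TSHB were not well above background in Stylo CSC and were at least 28.7-fold, 6.59-fold and 6.05-fold lower there.

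Of the genes tied to the sort, CD44 stood at 0.99 ± 0.14 and was not called, just under the fold limit. It was called with cyclic loess (1.00), quantile normalization (1.04), the detected-probe percentile (1.19), median scaling (1.42) and normexp (1.52). ALDH1A1 was not well above background on any of these 4 arrays, and no fold is given. ABCC1, a drug efflux pump, was 8.44-fold higher (3.08 ± 0.14), and drug transporters had 3 of 5 members higher. ABCB1 stood at 0.68 ± 0.11 and VIM at 0.21 ± 0.11, neither called. ABCB1 was called with median scaling (1.11) and normexp (1.20), and VIM with cyclic loess (1.47), quantile normalization (1.47) and normexp (1.82). CDH1 was at least 6.12-fold higher, with normexp giving -0.09. CD24, ALDH1A3, ABCG2, TOP2A and CDKN1A have no probe named here.

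Other list members with the largest change were THY1 (2.73 ± 0.13, another probe called lower), NPC1 (2.49 ± 0.27), TCF4 (1.28 ± 0.16) and VLDLR (1.17 ± 0.28) among the rises, and CYB5R3 at least 3.29-fold higher. MSMO1 (-2.43 ± 0.22), BIRC5 (-2.67 ± 0.44), PMAIP1 (-2.32 ± 0.15), SOD1 (-2.24 ± 0.14), CYCS (-2.11 ± 0.09), MME (-1.50 ± 0.09), COX8A (-1.22 ± 0.18) and VWF (-1.08 ± 0.31) fell, and ADIPOQ was at least 3.82-fold lower. CD79A was called lower (-1.73 ± 0.34) with 1 of 2 arrays of each group above background. Fibroblast markers rose in 4 of 6 and fell in 2, but the rises were COL1A1, COL1A2 and DCN, already counted among the collagens and matrix genes, and THY1. Lysosome and autophagy genes rose in 4 of 8 and fell in 1. Heat shock genes had no call among 4. Luminal epithelial genes had 1 rise and 2 falls among 4 measured members, and mesenchymal transition genes had 1 rise and 3 falls among 6.

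Of 26825 probes, 14484 were called, 5879 higher and 8605 lower in Stylo CSC, and 1094 of the calls, all lower, were on probes not well above background on any of the 4 arrays. Of the 978 named genes tested, 189 were higher and 371 lower. The series text states 28614 entities, and the count without the filter was 28650. Camera called ribosomal proteins (adjusted p = 0.000651; 0.394 with an estimated correlation), collagens and matrix genes (0.00257; 0.278), glycolysis and hypoxia (0.00398; 0.278), inflammatory cytokines (0.0150; 0.394) and drug transporters (0.0451; 0.394). The drug transporter call was lost with median scaling (0.0660), the detected-probe percentile (0.0547), cyclic loess (0.0856), quantile normalization (0.157), normexp (0.155), only the arrays compared (0.0531) and without Stylo parent replicate 1 (0.0680). The ribosomal call was lost with quantile normalization (0.361) and normexp (0.843), and the inflammatory call with normexp (0.522). All 4 arrays shared slide 1. Quantile normalization ended the calls of COX8A (-0.06), CYCS (-0.91), RPL19 (-0.64) and SOD1 (-0.84), cyclic loess those of COX8A (-0.33) and CD79A (-0.87), median scaling those of COX8A (-0.79) and VWF (-0.65), and the detected-probe percentile that of VWF (-0.88). Normexp ended those of CCL5 (0.46), CYCS (-0.52), MME (-0.98), MSMO1 (-0.90), PMAIP1 (-0.83), RPL19 (-0.80), SOD1 (-0.74), VLDLR (0.73) and VWF (-0.31), and turned COX8A (0.32), CYB5R3 (-0.64) and TCF4 (-0.15). Spike-in scaling ended those of SELENOT (-1.02), BIRC5 (-0.56), MSMO1 (-0.32), RPL19 (-0.27), PMAIP1 (-0.22), SOD1 (-0.14) and CYCS (-0.01). Calls ended without Stylo parent replicate 1 for VLDLR (0.81), without Stylo parent replicate 2 for VWF (adjusted p = 0.0902), without Stylo CSC replicate 1 for VLDLR (0.0516), and without Stylo CSC replicate 2 for VWF (0.0968), while CD44 was called without Stylo CSC replicate 2 (1.03) or Stylo parent replicate 2 (1.16).

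The third comparison put the sorted cells against the unsorted resistant subline. In Star CSC, all 6 tested interferon response genes rose: OAS1 by 2.04 ± 0.19, OAS2 by 1.69 ± 0.12, OAS3 by 1.48 ± 0.10, CXCL10 by 1.78 ± 0.09, MX1 by 3.05 ± 0.09 and OASL at least 12.8-fold. The co-stimulatory receptor CD86 (3.97 ± 0.25) and TYROBP, an adaptor of immune receptors that was not well above background in Star parent, rose as well, 2 of 3 tested leukocyte markers (list adjusted p = 0.126; median 2.20, turning to -0.25 with normexp). The matrix glycoprotein TNC fell 16.5-fold (-4.04 ± 0.14). Apoptosis regulators, 13 in number, had no call either way.

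Among genes well above background on all 4 arrays, the apolipoprotein APOA2 (5.36 ± 0.33), CD86, the betaine transporter SLC6A12 (3.42 ± 0.43), the protease inhibitor SLPI (3.17 ± 0.09) and MX1 rose most. After TNC, the potassium channel KCNA5 (-3.37 ± 0.33), the oxidase DUOX1 (-3.29 ± 0.27), RPE65 (-2.85 ± 0.19) and the immunoglobulin receptor PIGR (-2.70 ± 0.12) fell most. IFGGC1, FMO1 and OASL were not well above background in Star parent and were at least 28.5-fold, 19.4-fold and 12.8-fold higher in Star CSC. NCAM1, HTR1D and ADRA1B were not well above background in Star CSC and were at least 5.65-fold, 3.26-fold and 2.56-fold lower.

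ALDH1A1, one of the enzymes whose activity the sort can detect, was at least 3.09-fold higher in Star CSC, turning to -0.01 with normexp. CD44 stood at -0.88 ± 0.14, ABCB1 at 0.58 ± 0.11, ABCC1 at -0.58 ± 0.14, CDH1 at 0.98 ± 0.15 and VIM at -0.41 ± 0.11, none of them called. CDH1 was called with the detected-probe percentile (1.00), quantile normalization (1.096), cyclic loess (1.19) and median scaling (1.21). Inflammatory genes had 4 of 14 higher, CCL5 first (2.67 ± 0.24), and 1 lower, with a median of 0.27 that turned to -0.08 with normexp. CA9 (1.23 ± 0.15), DPT (2.16 ± 0.16) and KRT19 (2.34 ± 0.48, well above background on 1 of 2 Star parent arrays) rose. WNT5A (-1.84 ± 0.38), MME (-1.46 ± 0.09), FBN1 (-1.39 ± 0.09), ABCC4 (-1.31 ± 0.23), HMOX1 (-1.18 ± 0.20), CTSD (-1.16 ± 0.24) and MSMO1 (-1.08 ± 0.22) fell. None of the 22 ribosomal proteins was called, although the list as a whole was (median -0.56, or 1.09 with spike-in scaling; adjusted p = 0.00106, 0.590 with quantile normalization, 0.688 with normexp, 0.100 with spike-in scaling, and 0.602 with an estimated correlation).

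Of 26823 probes, 2608 were called, 863 higher and 1745 lower in Star CSC. Of the calls, 52, among them 48 lower, were on probes not well above background on any of the 4 arrays. Of the 978 named genes tested, 54 were higher and 72 lower. The series text states 1808 entities, and the count without the filter was 3227. The interferon list had an adjusted p of 1.1e-05 by camera, and adjusted p = 0.162 with an estimated correlation, although the estimate was negative (-0.057). By fry, which does not compare a list with other genes, its adjusted p was 3.0e-06. All 4 arrays shared slide 2. Without Star parent replicate 1, calls ended for ABCC4 (adjusted p = 0.0566), ADRA1B (0.0537), CTSD (0.0798), HMOX1 (0.0500), HTR1D (0.124), KRT19 (0.0722), MSMO1 (0.0648) and WNT5A (0.0874). Without Star parent replicate 2 they ended for ALDH1A1 (0.0636), CTSD (0.0582), HTR1D (0.0937) and MSMO1 (0.0602), without Star CSC replicate 1 for ALDH1A1 (0.0606), CTSD (0.0514), KRT19 (0.0588) and MSMO1 (log2 -0.74), and without Star CSC replicate 2 for ALDH1A1 (0.0660), CTSD (0.0826), HTR1D (0.135), KRT19 (0.0723) and WNT5A (0.0789). HTR1D also lost its call without either Stylo CSC array (0.0633), with median scaling (0.0567), cyclic loess (0.0823), quantile normalization (0.151) and normexp (log2 -0.81). Median scaling ended the calls of CTSD (-0.93), HMOX1 (-0.95) and MSMO1 (-0.85), and normexp those of ABCC4 (-0.85), ADRA1B (-0.75), HMOX1 (-0.97), KRT19 (0.26), MSMO1 (-0.86) and NCAM1 (-0.99). Spike-in scaling ended those of NCAM1 (-0.85), HTR1D (-0.19), WNT5A (-0.19) and ADRA1B (-0.12). CDH1 was called without Star CSC replicate 1 (1.11) or Star parent replicate 1 (1.09).

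**Figure D2:**
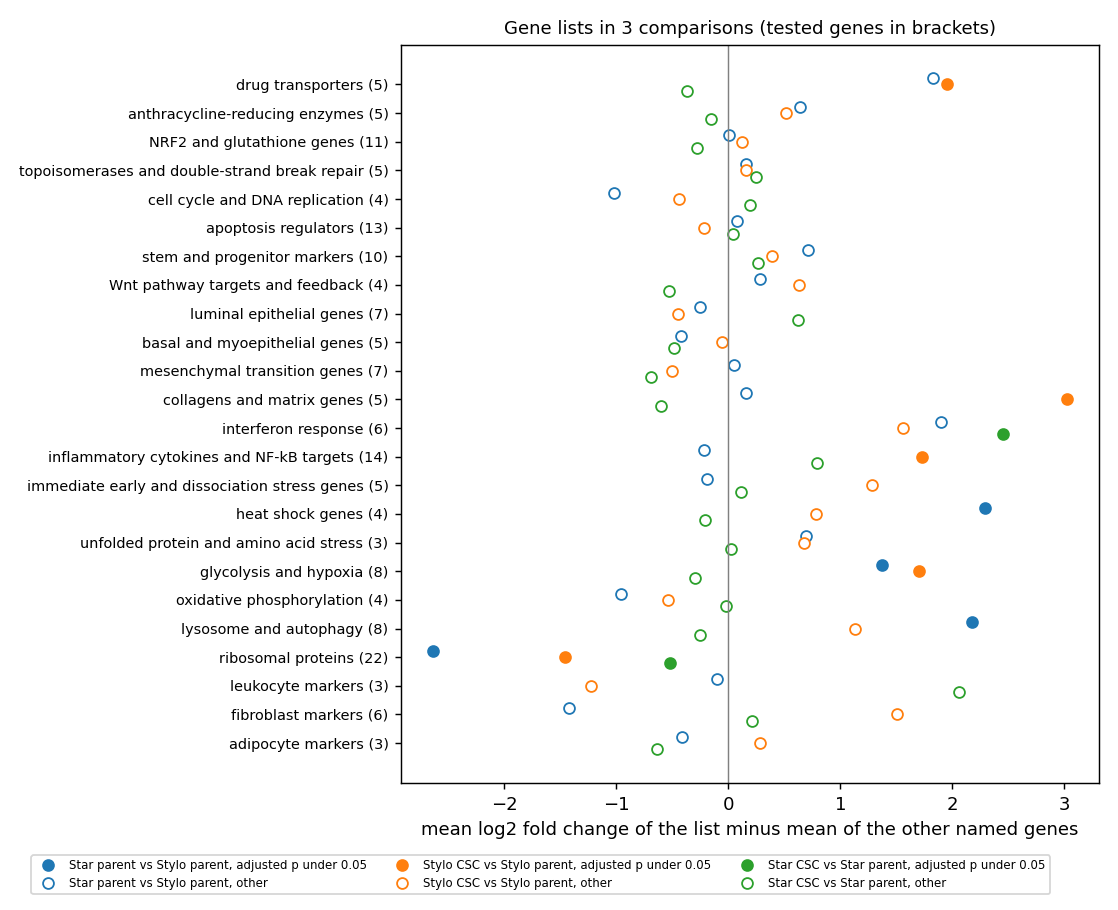
Mean log2 fold change of each gene list minus the mean of the other named genes, for 24 lists with at least 3 tested genes in the first 3 comparisons. Filled points have a camera adjusted p under 0.05. No list kept it with an estimated correlation, a version that could hardly call any list with 2 arrays per group. The interferon list is filled for Star CSC against Star parent, and ribosomal proteins are filled to the left of 0 in all 3, a call lost with quantile normalization in each.

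Star CSC was then set against Stylo CSC, a comparison that the layout implies. Collagens and matrix genes were lower in Star CSC in 5 of 5, with DCN at -7.00 ± 0.10 and COL1A1 at -6.27 ± 0.12. Interferon response genes were higher in 5 of 6, with MX1 at 3.87 ± 0.09. The leukocyte markers CD86 and TYROBP were higher, 2 of 3 tested (list adjusted p = 0.113; median 1.95, turning to -0.22 with normexp), and fibroblast markers were lower in 4 of 6, again the 3 shared with the collagen list and THY1, and higher in 1 (0.141). MAL (-7.70 ± 0.10), NR4A1 (-5.69 ± 0.15) and WNT5A (-5.58 ± 0.38) were also far lower, and GCG (7.54 ± 0.22), APOA2 (5.38 ± 0.33) and IL13RA2 (3.95 ± 0.13) higher, as was SMOC2 (16.03-fold). ABCB1 was 5.36-fold higher in Star CSC and ABCC1 6.36-fold lower, and ALDH1A1 was at least 2.72-fold higher, a call lost with normexp (0.23). CDH1 (-2.20 ± 0.15) and VIM (-1.95 ± 0.11; -0.33 with quantile normalization and -0.99 with cyclic loess, neither called) were lower, and CD44 stood at -0.80 ± 0.14, not called. Ribosomal proteins were lower in 19 of 22. In all, 7897 of 26823 probes were called, 3376 higher and 4521 lower. Of the calls, 97, among them 65 lower, were on probes not well above background on any array of the 2 groups. Of the 978 named genes tested, 154 were higher and 218 lower. Camera called ribosomal proteins (adjusted p = 1.2e-05), interferon response (0.000876) and collagens (0.0124), each 0.363 with an estimated correlation. The ribosomal call was lost with quantile normalization (0.108). Line and slide cannot be told apart here either.

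The last test asked whether the difference between sorted and unsorted cells itself differed between the lines. The Stylo parent arrays enter this test, so whatever sets them apart enters it too. Over all 978 named genes tested, 325 were called with a more positive change in the Star line and 204 with a more negative one. Over all probes, 13988 of 26823 were called, 7555 with a more positive change in the Star line and 6433 with a more negative one. The majority turned with median scaling (46.5% positive against 54.0%), the detected-probe percentile (47.5%), quantile normalization (46.6%), cyclic loess (48.1%) and spike-in scaling (32.4%). Among genes well above background on all 8 arrays, IL13RA2 (7.01 ± 0.19), SLPI (4.89 ± 0.13), PLAU (4.65 ± 0.30), CA2 (4.23 ± 0.84) and DPT (4.12 ± 0.22) had the most positive interaction. FBN1 (-4.44 ± 0.13), CCL2 (-3.98 ± 0.16), IGF2R (-3.87 ± 0.15), MYH9 (-3.84 ± 0.27) and BGN (-3.78 ± 0.21) had the most negative. ABCC1 (-3.66 ± 0.20) and CD44 (-1.87 ± 0.19) also differed, while ABCB1 (-0.10 ± 0.15) and VIM (-0.62 ± 0.16) were not called. No interaction is given for CDH1, which was not well above background in Stylo parent, or for ALDH1A1, which was so only in Star CSC. VIM gained a call with cyclic loess (-1.61), quantile normalization (-1.31) and normexp (-2.20). All 5 collagens and matrix genes and 7 of 8 glycolysis and hypoxia genes had a negative interaction (adjusted p = 0.00189 for both lists; 0.223 with an estimated correlation). Ribosomal proteins had a positive one in 15 of 22 (0.00236; 0.431 with an estimated correlation), with a median of 1.26 that became -0.04 with quantile normalization and -0.22 with normexp. That call was lost with both (0.847 and 0.316), with cyclic loess (0.240) and with spike-in scaling (0.136). The interferon list had 4 of 6 members more positive and 1, MX1, more negative. It did not pass camera (adjusted p = 0.742), which compares a list with the other named genes and does not test the list's own change. MX1 was not well above background in Stylo parent, and OASL was so only in Star CSC, so their interactions carry no size. MX1 and CXCL10 rose in Stylo CSC as well.

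**Figure D3:**
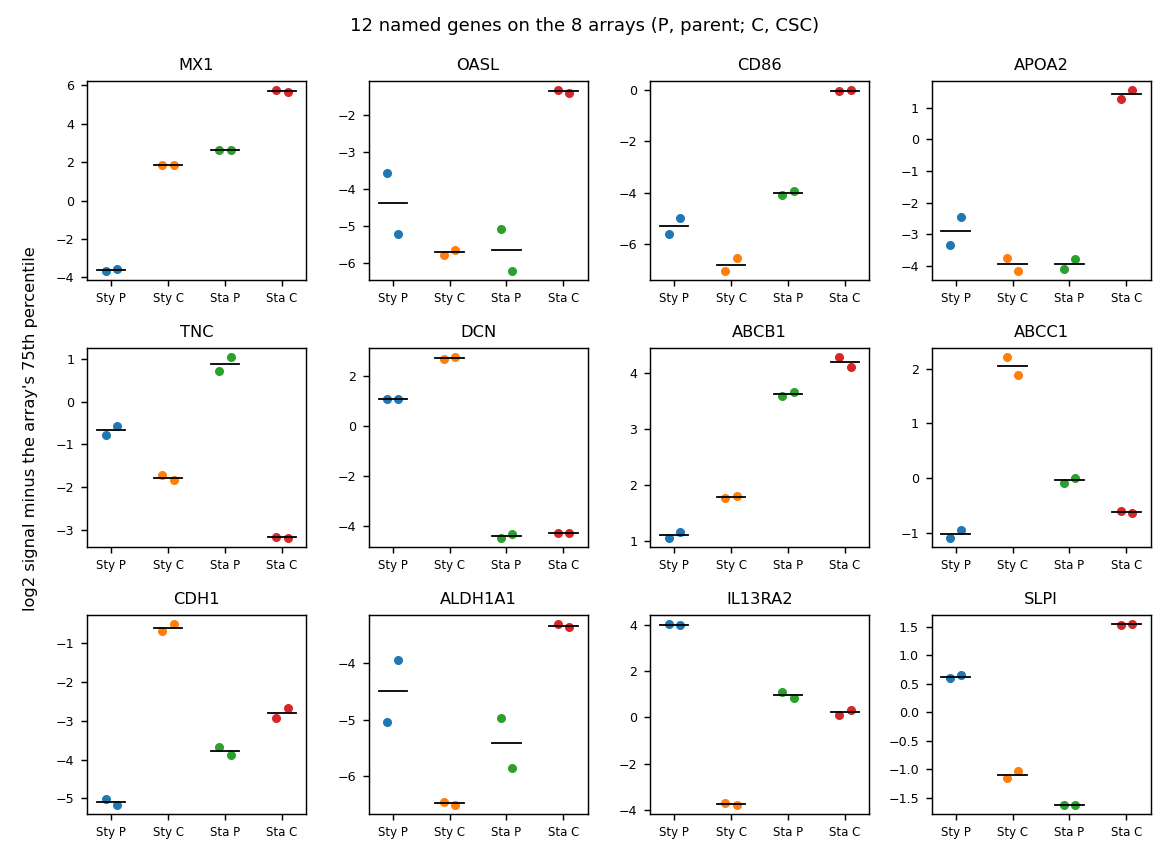
Log2 processed signal minus the array's 75th percentile for 12 named genes. Points are single arrays, lines are group means, and the groups from left to right are Stylo parent, Stylo CSC, Star parent and Star CSC. OASL is well above background in Star CSC alone, and IL13RA2 is lower in Stylo CSC than in Stylo parent (-7.74).

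Star parent against Stylo parent and Stylo CSC against Stylo parent moved alike across probes, with a Pearson r of 0.781 over 26825 probes, which are not independent replicates. Both use the same Stylo parent arrays. In 100 simulations of unchanged groups against those arrays r averaged 0.502 (highest 0.544). The covariance was 2.14 against 0.0435 simulated. Of the calls, 4533 were higher in both and 6348 lower in both, where independent lists would share 1446 and 2748. With a different Stylo parent array under each comparison, a check added after this result was seen, r was 0.745 and 0.747 and the covariance 2.08 both ways. Both arrays come from the same group, so what they share still enters both comparisons.

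Changes are relative to each array's 75th percentile. Scaling each array to its median instead moved all log2 fold changes by a constant, 0.40 for Star parent against Stylo parent, 0.43 for Stylo CSC against Stylo parent, 0.23 for Star CSC against Star parent and 0.20 for Star CSC against Stylo CSC. The share of calls that were higher went from 43.5% to 56.9%, from 40.6% to 57.2%, from 33.1% to 58.7% and from 42.8% to 56.2%. Of the genes picked by the naming rule and called, all 42, 38, 28 and 15 of the first 4 comparisons had both arrays of one group beyond both arrays of the other. They were picked because they were called, so this outcome was close to fixed by the selection and adds no support.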

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

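The tests of array scaling, of dim probes, of leukocytes and of dissociation stress were chosen after the results were seen. The test on probe pairs was written before its result was seen.

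The effect of sorting differed between the lines for 13988 probes by the interaction test. By the same test it differed for FBN1 (-4.44), CCL2 (-3.98), IGF2R (-3.87), MYH9 (-3.84), BGN (-3.78), ABCC1 (-3.66) and CD44 (-1.87), all with a more negative change in the Star line. It differed the other way for IL13RA2 (7.01), SLPI (4.89), PLAU (4.65), CA2 (4.23) and DPT (4.12). CDH1 (-3.51) and ALDH1A1 (4.04) were called too, but CDH1 was not well above background in Stylo parent and ALDH1A1 was so only in Star CSC, so these values carry no size and are not read as a difference. Among lists, the mean interaction less that of other named genes was -3.62 for collagens and matrix genes, -2.00 for glycolysis and hypoxia and 0.95 for ribosomal proteins. None of these list calls held with an estimated correlation (adjusted p = 0.223, 0.223 and 0.431), and the ribosomal value turned to -0.31 with normexp and lost its call with quantile normalization and cyclic loess. The lines lay on separate slides, and an additive slide effect cancels in the interaction. Whatever sets the Stylo parent arrays apart does not cancel, since that group enters the interaction. Its 13988 calls lay near the 14484 of Stylo CSC against Stylo parent, while Star CSC against Star parent had 2608. These differences between the lines may therefore reflect the Stylo parent arrays.

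Comparisons with the Stylo parent arrays called 15168 and 14484 probes, against 2608 for Star CSC against Star parent. Scaling to the 75th percentile does not make the Stylo parent arrays stand apart in correlation, which no constant per array can move: Stylo CSC and Stylo parent arrays correlated at 0.889 at most, and Star CSC and Star parent arrays at 0.953 or more. Signal near background is not the whole cause of the contrast in counts: of the 18423 probes detected on all 8 arrays, 53.9% were called with this scaling, against 7.35% for Star CSC against Star parent. Scaling stays open for the counts. Quantile normalization still called 13755 probes for Stylo CSC against Stylo parent, but it equalises the arrays too. Spike-in scaling gave 15549 and 18364 calls against 21619 for Star CSC against Star parent, which reverses the order. The spike-ins themselves were brighter on the Star parent arrays (11.75 and 11.26 on the log2 scale) than on the Star CSC arrays (10.45 and 10.30). Part of the shift behind the 21619 calls, 99.2% of them higher, is therefore spike signal, so the reversal cannot decide. The spike-in condition was added to this test after both counts were seen; with the first bound, on quantile normalization alone, scaling would have been argued against. Loss of signal by probe position along a transcript stays open: different probes of the same transcript correlated at 0.786, between the bounds set in advance for and against it, and at 0.858 among pairs detected on all arrays. A state of the parent culture that differs from the other cells also stays open, untested.

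Without the filter on dim probes, Stylo CSC against Stylo parent had 28650 calls, near the 28614 entities in the series text. The same count was 3227 for Star CSC against Star parent, where the text states 1808, so the match does not extend to it. These are calls by adjusted p, and the series text names no correction. With an unadjusted p under 0.05 and 2-fold the counts were 28977 and 4639. Of the 28650, 14862 were on probes not well above background on any of the 4 arrays, and 100% of those went down. All 17847 probes of that kind had a median change of 0.38 before scaling and -1.57 after it. Dim probes lowered by the scaling are a candidate explanation for about that part of the unfiltered count, and no biological explanation for it was tested.

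The 6 interferon response genes rose in Star CSC. Stress from dissociation stays open, since the few immediate early genes tested cannot decide it. Their median change was 0.0483 over 5 tested members of 33 listed (SD 0.65), below the rise of 1 that such stress was taken to need. It also lay under the bound set against stress, and under 1 by more than the SD, so the rule of this test went against stress. That verdict is not relied on, with so few members and a median that depends on the scaling. The members were mixed, with ID3 at 0.99 and FOSB at -0.63. With spike-in scaling, which shifted all changes up, their median was 1.69. Leukocytes among the sorted cells stay open: 3 of 9 named leukocyte markers were well above background on both Star CSC arrays (CD79A, TYROBP and CD86), and CD79A and CD86 were so in Star parent too. The bound against leukocytes was changed, after this count was seen, from at most 3 of 9 to fewer than 3 of 9; under the first wording the count would have argued against them. The median change of the 3 tested markers, 2.20, turned to -0.25 with normexp. The cells were sorted from a cell line and not from tissue, so the design itself names no source of leukocytes. The sort used CD44, CD24 and aldehyde dehydrogenase activity, and the labels name no marker that would remove leukocytes. A response of the resistant stem-like cells themselves is the biological alternative and was not tested.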

How the results depend on the processing

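Spike-in scaling, a different Stylo parent array under each comparison, the fits without the Stylo parent group, the adjusted unmoderated test and gene and list values from only the arrays compared were chosen after seeing the data. Every count was within 1.5 times its value in the report under median scaling, cyclic loess, quantile normalization, the detected-probe percentile, the deposited matrix, flagged spots left in, the trend and robust variance model and an unadjusted p. With the replicate block the counts were 15148, 14459, 2525, 7867 and 13942 for the 5 contrasts in the order of the report, and it ended no call of a named gene. The slide block left the 2 sorting counts and the interaction as they were, since the groups already absorb it, and it could not be fitted for comparisons across lines. Within slides, the fits on only the arrays compared called 14569 probes for Stylo CSC and 2434 for Star CSC, and MSMO1 lost its call in the latter (adjusted p = 0.0610), as did PTGS2 in Star parent against Stylo parent (0.0510).

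Leaving out each array gave 14739 to 15235, 13835 to 14574, 2180 to 2992, 7078 to 8046 and 13086 to 13845 calls, and an r of 0.770 to 0.791; a lone array was assumed to vary like the other groups. Without the filter, counts were 26734, 28650 and 21988 for Star parent, Stylo CSC and the interaction. With only probes detected on all 8 arrays, fewer probes were tested and Star CSC against Star parent had 1354 calls and against Stylo CSC 4581. With normexp these 2 had 1143 and 4019, and r was 0.864; quantile normalization gave an r of 0.815. With no minimum fold they had 7922 and 15288. The unmoderated test with adjusted p called 318 for Star CSC against Star parent. Spike-in scaling called 21619 for it and 8340 for the interaction. Except where fewer probes were tested, the cause was not tested.

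The share of calls that were higher, 43.5% for Star parent against Stylo parent, was 54.5% with the detected-probe percentile, 55.3% with quantile normalization, 25.2% with normexp and 76.5% with spike-ins. For Stylo CSC against Stylo parent (40.6%) it was 53.9% with quantile normalization, 51.8% with loess, 25.8% with normexp and 98.4% with spike-ins. For Star CSC against Star parent (33.1%) it was 46.7% with quantile normalization, 47.5% with loess and 99.2% with spike-ins, and against Stylo CSC (42.8%) 52.9% with the detected-probe percentile and 75.4% with spike-ins. For the interaction (54.0%) it was 70.1% with normexp, 32.4% with spike-ins and 46.5% to 48.1% with the other 4 scalings. Spike-in scaling shifted all changes by 1.05, 2.10, 1.64, 0.59 and -0.46.

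Direction turned with normexp for ALDH1A1 in Star CSC against Star parent (-0.0116), for CDH1 (-1.65), KDR (-1.41), MSMO1 (0.18) and VIM (0.10) in Star parent, and for CDH1 (-0.0868), COX8A (0.32), CYB5R3 (-0.64) and TCF4 (-0.15) in Stylo CSC. For VIM in Star parent it turned with cyclic loess (0.62) and quantile normalization (0.98), and for TYROBP with quantile normalization (0.0177), where neither group was above background and the value has no direction. With spike-ins it turned in Stylo CSC for ADIPOQ (0.17), ALDH1A1 (0.12, neither group above background), CD79A (0.37), COX8A (0.88), MME (0.61) and VWF (1.02), and in Star CSC against Star parent for ABCC1 (1.06), ABCC4 (0.33), CTSD (0.48), FBN1 (0.26), HMOX1 (0.46), MME (0.18), MSMO1 (0.56) and VIM (1.23). They ended 17 gene and 4 list calls without turning them, in the report except for TYROBP.

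With normexp the ribosomal list fell to -0.0105 relative to other genes in Stylo CSC, where camera, which works on test statistics, called its direction up, and it turned in the interaction (-0.31). The direction given by fry, which does not compare a list with other genes, differed from that of camera for anthracycline-reducing enzymes (down, although the mean was 0.13 in Star parent and 0.14 in Stylo CSC), cell cycle (-0.81 in Stylo CSC), collagens (-0.35) and mesenchymal genes (-0.45) in Star parent, NRF2 genes (-0.50 in Star parent, -0.25 in Stylo CSC) and topoisomerases (-0.35 in Star parent, -0.21 in Stylo CSC, 0.40 in the interaction). No call of the 25 lists set in advance held with an estimated correlation, whether above or below 0.01. With 2 arrays per group that version has few residual degrees of freedom, so this outcome was close to fixed. It does not tell whether the genes of a list are correlated.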

Other observations

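A list of MHC and immunoproteasome genes, chosen after the data were seen, was higher in Star CSC than in Stylo CSC in 13 of 13 tested members (median log2 1.62). Against Star parent, 4 of 13 rose in Star CSC and none fell. The leukocyte markers CD86 and TYROBP were higher in Star CSC in both of these comparisons, so leukocytes stay open for this list too. Among the 4 rises were the immunoproteasome subunits PSMB8 (2.53 ± 0.39) and PSMB9 (2.51 ± 0.11) and the class II gene HLA-DRB1 (2.71 ± 0.11). The camera p was 2.0e-07 and 0.00519 with an estimated correlation, for a list picked on these arrays. In Stylo CSC against Stylo parent, the same list had 7 members higher and 3 lower (p = 0.0139; 0.0597 with an estimated correlation). In Star parent against Stylo parent 6 were higher and 1 lower (p = 0.00354; 0.0365 with an estimated correlation), and the interaction had p = 0.774.

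Against the spiked-in control transcripts, the 75th percentile of the sample signal lay lowest on the Stylo parent arrays (-3.60 and -4.60 on the log2 scale) and highest on the Star CSC arrays (-1.37 and -1.43). Stylo CSC arrays lay at -2.17 and -1.82 and Star parent arrays at -3.21 and -2.89. The spike-ins themselves were brightest on the Star parent arrays (11.75 and 11.26 on the log2 scale), which lowers the Star parent values.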
